A study of Mus musculus with 14 samples.

How the data were processed

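RNA of plantaris muscle was measured on 14 Affymetrix Mouse Gene 1.0 ST arrays, 2 for each of 7 days of overload, one from a pool of right muscles and one from a pool of left muscles. Each pool held muscle of 6 animals, per the labels. The labels give 100 ng of total RNA in one place and 250 ng in another for the labelling reaction. The deposited values are intensity values on a linear scale, 1 per probe set, which the authors made with Partek software, whose version is not given. The method of summarising and normalizing is not stated in the labels. The array medians lie close together, between 242.8 and 254.9, so the arrays appear to have been scaled to each other before deposit. Intensities ranged from 5.9 to 29501.5. On arrays the number of samples, not a read depth, limits the precision.

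The log2 of the deposited intensity was used without further normalization. Of 35556 probe sets, 21789 carried exactly 1 gene symbol, 1621 carried several, and 12146 were not listed in the probe annotation. For the 999 genes with several probe sets the one with the highest mean over all arrays was used, and in 41 of these genes the probe sets were called in opposite directions at day 7. This left 19938 genes. Gene symbols were checked against a RefSeq gene table by gene number, and 0 needed an update. No genome coordinates are given, because the genome build of the array annotation is not stated.

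Each gene was fitted in limma 3.58.1 under R 4.3.3, with 1 mean per day and all 14 arrays, which leaves 7 residual degrees of freedom, and with the default variance prior, which added 3.88. The 12 contrasts were: 6 days against day 0, 5 of consecutive days, and day 14 against day 3. P-values were adjusted by Benjamini-Hochberg over all genes within each comparison, and a gene was called changed at an adjusted p under 0.05. All tests were two-sided. A moderated F test covered the 6 contrasts against day 0. Right and left pools were compared in a fit with day and side. With 2 arrays per day no test for outlying arrays and no count over other splits of the samples was made.

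Gene groups were 39 lists written from general knowledge, with 927 members, of which 860 were measured. Some lists share members, so their results are not independent. C1qa, C1qb and C1qc are in the complement and macrophage lists, and Tnni1 is in the developmental and slow sarcomere lists. Sdha and Sdhb are in the oxidative phosphorylation and tricarboxylic acid cycle lists. Each list was tested against day 0 with limma's camera at its preset correlation of 0.01, again with a correlation estimated from the data, and with fry, and the p-values were adjusted over the 234 pairs of list and day. The fits, contrasts, thresholds, lists, rules for naming genes and the alternatives listed first below were fixed before the data were examined. A lookup of gene synonyms had at first placed Loxl3, Olfr48 and Pigq in the lists by mistake, and this was corrected after results had been seen, with the lists as written unchanged. Genes were named by rule: at each day the 10 largest rises and 10 largest falls among called genes whose 2 arrays both lay on one side of both day 0 arrays, for the other comparisons the 5 largest each way, up to 4 members per list and day, and a panel of 34 genes. Gene models, olfactory and vomeronasal receptors, small RNAs, receptor segments and Y-linked genes were counted but not named. The rule gave 365 genes, of which 20 lay in the dimmest class and 14 had several probe sets.

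After the data were seen 4 lists were added: genes of hepatocytes, granule genes of neutrophil precursors in marrow, genes of mature neutrophils, and imprinted genes. Alternatives fixed beforehand were quantile normalization, equal array medians, leaving out the dimmest of 3 equal classes of genes, averaging a gene's probe sets, using all probe sets, a trended or robust variance prior, side as a replicate block, fitting only the arrays of the 2 days compared, a 2-fold threshold, limma's treat against 1.5-fold, and leaving out each array in turn. Leaving out an array leaves its day with 1 pool, whose spread is then taken from the other days. Alternatives added later were the mean of the hepatocyte genes as a covariate, and leaving out the left pool of day 0 and the right pool of day 1 together. The latter sets the left pool of day 1 against the right pool of day 0, so there day and side cannot be told apart.

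The pipeline was tested on simulated data in which day 3 differed from day 0 by a known fold, in 50 genes at each of 4 sizes. It recovered 86% of genes changed by 1.5-fold, 98% at 2-fold, 100% at 4-fold and 100% at 8-fold, with 11 false calls among all genes. With no change added it made 0 calls. Camera found the shifted list and called 0 others. The simulated genes varied independently of each other, so this could not show how camera behaves among correlated genes. Figures were drawn with matplotlib 3.10.9.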

Results

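The series followed gene expression in the plantaris muscle of male C57BL/6J mice, 5 months old, over 14 days of functional overload. Overload was produced by synergist ablation, the surgical removal of muscles that share the plantaris's task, after which the plantaris grows. RNA was measured on Affymetrix Mouse Gene 1.0 ST arrays, which read each gene with probes spread along its transcript. Muscle was taken at day 0 and at days 1, 3, 5, 7, 10 and 14, and each day had 2 arrays, one of a pool of right plantaris muscles and one of a pool of left plantaris muscles, each pool from 6 animals. The 14 arrays gave intensities from 5.9 to 29501.5, with array medians between 242.8 and 254.9. The number of arrays limits the precision, and the median standard error of a difference between 2 days was 0.0988 on the log2 scale. The labels do not say whether the right and left muscles of a day came from the same animals, so the p-values measure only the spread between pools, which may be partly technical, and not the spread between animals. Changes below are log2 differences between day means ± SE from the fit, with 2 pools at each day.

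Most of the genes measured changed over the time course. No sham-operated group is among the samples, so effects of surgery and of time cannot be told apart from those of overload. The moderated F test over all days called 14211 of 19938 genes, and against day 0 the number called was 10970 at day 1, 9502 at day 3, 12980 at day 5, 13206 at day 7, 10192 at day 10 and 8394 at day 14. Of these, 1852, 2356, 2579, 3043, 1842 and 1233 changed by more than 2-fold. Among the genes past 2-fold more rose than fell at each day, for example 1930 against 1113 at day 7 and 976 against 257 at day 14. The median over all genes lay slightly below day 0 at each day, between -0.07 at day 3 and -0.16 at day 5, and another scaling of the arrays moved it by less than 0.1. This shift was not subtracted from the changes given here. The share of called genes that rose was 36.9% at day 1, 50.8% at day 3, 41.5% at day 5, 43.0% at day 7, 46.1% at day 10 and 50.9% at day 14. Which direction held more calls depended on the processing at each day but day 1. Without the dimmest of 3 equal classes of genes the share was 52.4%, 53.02% and 52.8% at days 5, 7 and 10. At days 3 and 14 it was 47.8% and 46.3% under quantile normalization, 48.4% and 43.1% with equal array medians, and 49.1% and 49.95% without the left pool of day 0 and the right pool of day 1. It also crossed over at day 3 without the left pool of day 0 (49.6%) and at day 14 without either pool of day 1 (49.5%). At day 10 it did so without the right pool of day 0 (50.7%), the right pool of day 10 (51.3%) or the left pool of day 10 (50.02%).

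**Figure D1:**
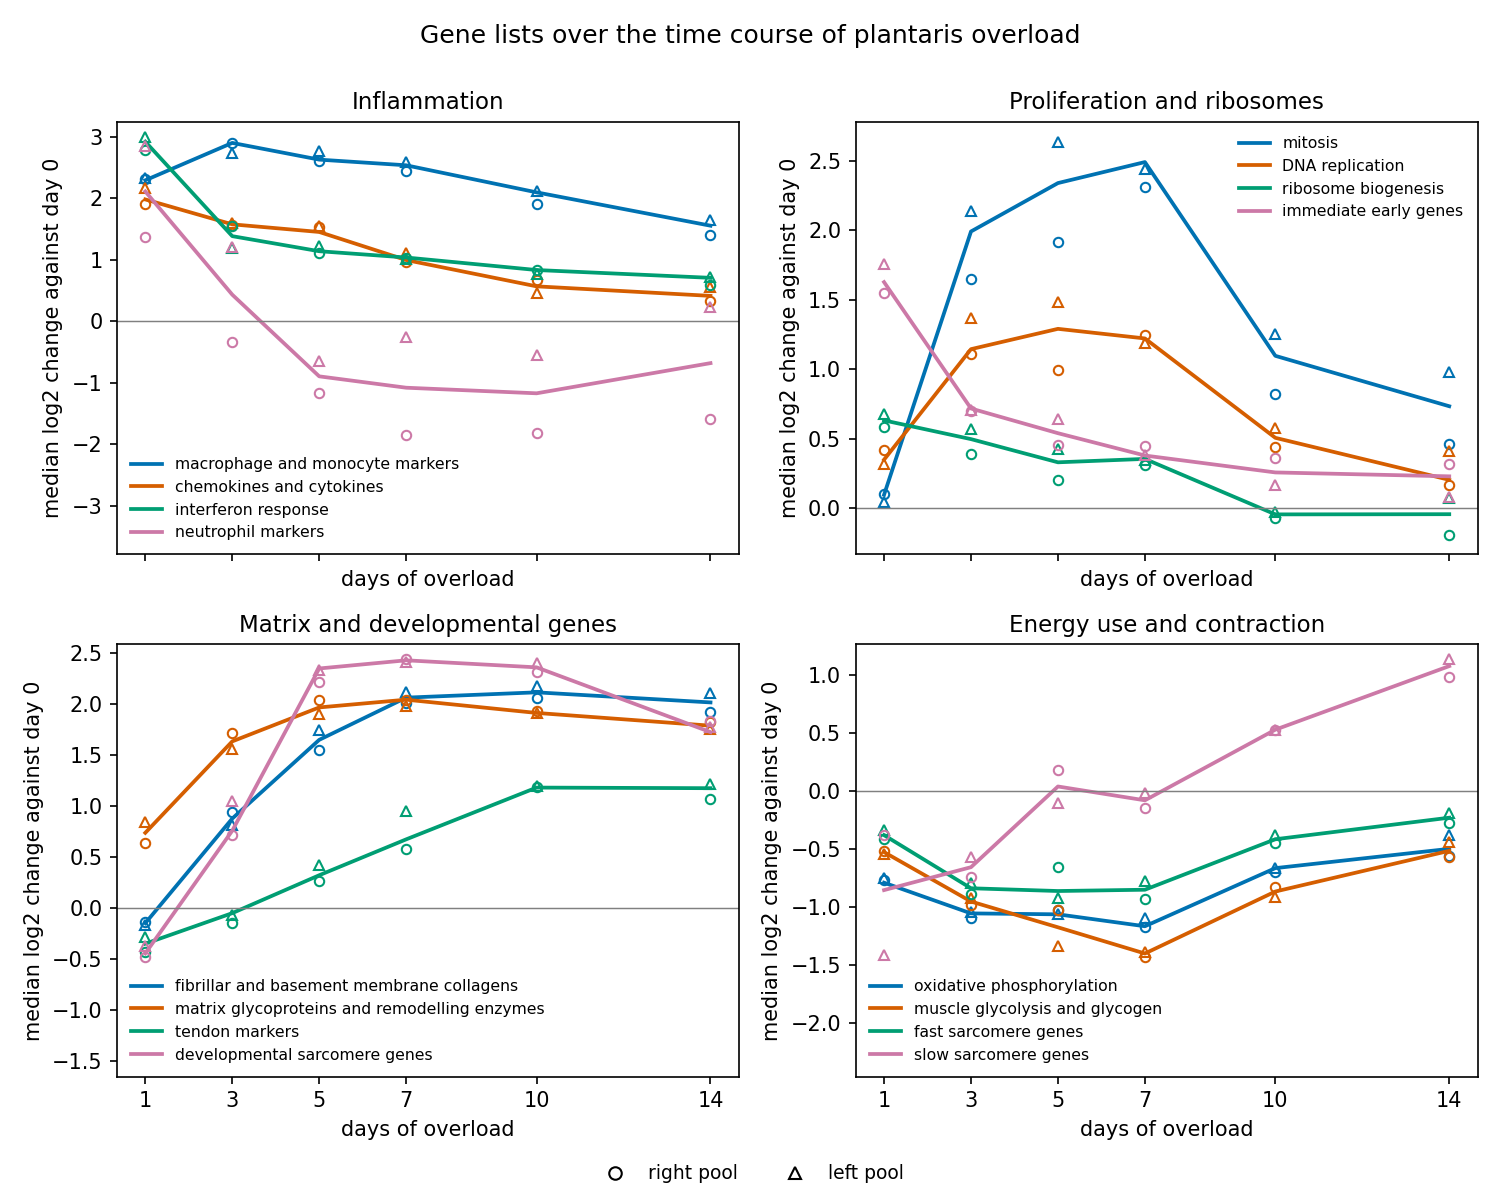
Median log2 change against day 0 (vertical axes, log2 units) of 16 of the fixed gene lists at each day of overload (horizontal axes, days), with lines for the mean of both pools, circles for the right pool and triangles for the left pool. Slow sarcomere genes stood highest at day 14 with a median of 1.07, while macrophage markers peaked at day 3 and mitosis genes at day 7 in the right pools and both at day 5 in the left pools.

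After 1 day, genes of inflammation, of stress responses and of ribosome production stood above day 0, and genes of energy metabolism stood below it. The largest rises were of the chemokine Ccl3 (5.52 ± 0.15), the Schlafen family gene Slfn4 (5.51 ± 0.13), the chemokine Cxcl2 (5.20 ± 0.28) and the leukocyte receptors Clec4e (5.19 ± 0.20) and Cxcr2 (5.14 ± 0.35), and Ccl2 (4.83 ± 0.12), the monocyte chemokine, rose 28.5-fold. Of the chemokines and cytokines, 26 of 30 rose and 2 fell (camera adjusted p = 1.42e-16, and 0.0135 with an estimated correlation), and the eosinophil chemokine Ccl11 (-1.01 ± 0.12) was among those that fell. Of the macrophage and monocyte markers, 26 of 30 rose and 1 fell (camera adjusted p = 2.15e-17, and 0.0354 with an estimated correlation), among them Itgam (3.86 ± 0.19) and Msr1 (3.72 ± 0.13). Of the neutrophil markers, 10 of 15 rose and 0 fell, led after Cxcr2 by Csf3r (4.19 ± 0.22), the receptor of granulocyte colony-stimulating factor (camera adjusted p = 5.19e-05, and adjusted p = 0.300 with an estimated correlation). At days 0 and 1, granule genes of developing neutrophils were higher in the right pool than in the left, by a median of 0.91 and 1.28. Of the interferon response genes, 16 of 16 rose and 0 fell, with Ifit1 (4.04 ± 0.16) and Ifit3 (4.04 ± 0.17) in front (camera adjusted p = 2.01e-15, and adjusted p = 0.0802 with an estimated correlation). Lymphocyte markers went both ways, and 2 of 18 rose and 2 fell (camera adjusted p = 0.557). Of the complement components 5 of 12 rose and 2 fell (camera adjusted p = 0.00861, and adjusted p = 0.352 with an estimated correlation), and the anaphylatoxin receptors C3ar1 (3.76 ± 0.09) and C5ar1 (3.32 ± 0.12) led. The call of the complement list ended without the right pool of day 0 or of day 1, at an adjusted p of 0.0747 and 0.0697.

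Immediate early genes, which respond to growth and stress signals within hours, were raised at day 1. Of this list 20 of 23 rose and 0 fell (camera adjusted p = 8.86e-14, and 0.0226 with an estimated correlation), with Myc (3.86 ± 0.09), Fosl1 (3.41 ± 0.19) and Atf3 (3.21 ± 0.10). Of the genes of endoplasmic reticulum stress and folding 26 of 27 rose and 1 fell (camera adjusted p = 1.50e-18, and 0.0337 with an estimated correlation), with Ero1a (3.84 ± 0.12), an oxidase that helps form disulfide bonds, and Asns (2.48 ± 0.13), the asparagine synthetase. Amino acid transport and polyamine synthesis genes rose in 12 of 16 cases and fell in 0 (camera adjusted p = 2.19e-09, and 0.0469 with an estimated correlation), with Slc7a11 (3.70 ± 0.20) and Slc7a5 (2.62 ± 0.10). Of the ribosome biogenesis genes 34 of 44 rose and 1 fell (camera adjusted p = 3.81e-13, and adjusted p = 0.230 with an estimated correlation), led by Nop58 (1.78 ± 0.12) and Gnl3 (1.61 ± 0.11). Rrs1, also a ribosome assembly factor, stood at 0.08 ± 0.16 and did not pass the test. Translation factors rose in 13 of 27 cases and fell in 2 (camera adjusted p = 5.73e-05, and adjusted p = 0.215 with an estimated correlation), with Eif1a (2.26 ± 0.10) and Eif4a1 (1.32 ± 0.07). Antioxidant and heme response genes rose in 10 of 19 cases and fell in 5 (camera adjusted p = 0.000612, and adjusted p = 0.215 with an estimated correlation). Heme oxygenase Hmox1 (3.65 ± 0.09) and metallothionein Mt1 (3.16 ± 0.08) were highest, and mitochondrial superoxide dismutase Sod2 (-0.63 ± 0.08) fell.

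Genes of energy metabolism fell at day 1. All 21 tricarboxylic acid cycle genes fell (camera adjusted p = 7.45e-08, and adjusted p = 0.236 with an estimated correlation), with Idh2 (-1.63 ± 0.11) lowest. Of the oxidative phosphorylation genes 0 of 42 rose and 40 fell (camera adjusted p = 1.24e-11, and adjusted p = 0.219 with an estimated correlation). Of the genes of fatty acid uptake and oxidation 1 of 26 rose and 25 fell (camera adjusted p = 6.02e-09, and adjusted p = 0.236 with an estimated correlation). The rise was that of Pdk4 (0.63 ± 0.10), a kinase that shuts pyruvate out of the cycle. Of the genes of muscle glycolysis and glycogen 1 of 22 rose and 12 fell (camera adjusted p = 0.0111, and adjusted p = 0.580 with an estimated correlation). The insulin-responsive glucose transporter Slc2a4 (-2.04 ± 0.18) fell and hexokinase Hk2 (1.32 ± 0.11) rose. Excitation-contraction coupling genes fell in 16 of 17 cases (camera adjusted p = 3.95e-06, and adjusted p = 0.321 with an estimated correlation), with Stac3 (-1.57 ± 0.10). Of the fast sarcomere genes 0 of 22 rose and 12 fell (camera adjusted p = 0.0146, and adjusted p = 0.615 with an estimated correlation), and the adjusted p was 0.0734 without the left pool of day 0 and the right pool of day 1. Of the slow sarcomere genes 2 of 14 rose and 9 fell (camera adjusted p = 0.0478, and adjusted p = 0.456 with an estimated correlation). That call is marginal, as its adjusted p was 0.0612 under quantile normalization, 0.0536 and 0.0565 without the right or left pool of day 0 and 0.121 without the left pool of day 1, and it also ended without single pools of later days. The largest falls of all were of Lrrc30 (-3.10 ± 0.15), Ky (-3.02 ± 0.14), Ddit4l (-3.02 ± 0.11) and Timp4 (-2.69 ± 0.15). Atrophy-linked ubiquitin ligases and FoxO genes were split, as 9 of 20 rose and 6 fell (camera adjusted p = 0.195). The muscle ubiquitin ligase Trim63 (1.77 ± 0.09) rose while Mstn (-1.15 ± 0.19), the growth inhibitor myostatin, fell. Of the mechanical load and Z-disc stress genes 10 of 26 rose and 8 fell (camera adjusted p = 0.0508), with the titin-binding stress gene Ankrd1 (4.64 ± 0.13) and Xirp1 (2.14 ± 0.14) higher. Satellite cell and myogenic regulators fell in 14 of 25 cases and rose in 5 (camera adjusted p = 0.281), and the stem cell factor Pax7 (-0.59 ± 0.09) was lower.

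At day 1 the DNA replication genes rose in 13 of 29 cases and fell in 1 (camera adjusted p = 0.00108, and adjusted p = 0.514 with an estimated correlation). Of the mitosis genes 3 of 34 rose and 1 fell (camera adjusted p = 0.137). Adjusted over the list alone, 0 mitosis genes rose and 0 fell. The call of the replication list ended without the left pool of day 0 and the right pool of day 1, the pools with the most hepatocyte signal. That fit sets the left pool of day 1 against the right pool of day 0, so it mixes day with side. The proliferation gene Mki67 stood at 0.28 ± 0.38 and did not pass the test, with its right pools above its left pools at both days. Of the cyclin-dependent kinase inhibitors and p53 targets 7 of 16 rose and 6 fell (camera adjusted p = 0.0906), led by the growth arrest gene Gadd45a (2.81 ± 0.08). Fibro-adipogenic progenitor markers fell in 13 of 19 cases and rose in 4 (camera adjusted p = 0.0819). Schwann cell and nerve markers fell in 8 of 13 and rose in 1 (camera adjusted p = 0.360). Among the endothelial markers 4 of 20 rose and 8 fell (camera adjusted p = 0.833), yet the vessel growth peptide Apln (3.06 ± 0.12) was higher. Circadian clock genes went both ways, as 4 of 17 rose and 8 fell (camera adjusted p = 0.813), with Nfil3 (1.36 ± 0.10) and Dbp (-1.57 ± 0.09) at the ends. The labels do not give the time of day at which muscle was taken, on which these genes depend. Adjusted over the list alone, 27 of the 39 lists kept the same counts at day 1. No list's count of rises, and no list's count of falls, differed by more than 3.

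At day 3, genes of inflammation, cell division and matrix stood above day 0, and genes of energy metabolism stood below it. Matrix glycoproteins and remodelling enzymes had already risen at day 1, in 25 of 35 cases, and fallen in 6 (camera adjusted p = 5.91e-10, and adjusted p = 0.0981 with an estimated correlation). The largest rises were of Ms4a6d (5.15 ± 0.09), Timp1 (5.06 ± 0.11), an inhibitor of matrix proteases, Ccl2 (4.65 ± 0.12) and Ms4a4a (4.56 ± 0.10), and the collagen cross-linking enzyme Lox (4.02 ± 0.08) rose 16.2-fold. All 34 mitosis genes rose (camera adjusted p = 2.58e-15, and adjusted p = 0.236 with an estimated correlation), with a median of 1.99 and with Ccna2 (2.96 ± 0.29) and Plk1 (2.96 ± 0.18) highest. The proliferation gene Mki67 rose by 2.20 ± 0.38 and the topoisomerase Top2a (2.68 ± 0.28) rose with it. Of the DNA replication genes 28 of 29 rose and 0 fell (camera adjusted p = 1.58e-11, and adjusted p = 0.236 with an estimated correlation), with the ribonucleotide reductase subunit Rrm2 (2.81 ± 0.24). Macrophage and monocyte markers had a median of 2.90, and 28 of 30 rose and 1 fell (camera adjusted p = 9.98e-19, and 0.0337 with an estimated correlation), with Ms4a7 (3.89 ± 0.07) and Cd68 (3.62 ± 0.08). Of the collagens 16 of 18 rose and 0 fell (camera adjusted p = 5.17e-09, and adjusted p = 0.163 with an estimated correlation), with Col1a1 (1.97 ± 0.09) and Col3a1 (2.03 ± 0.08), and of the matrix glycoproteins and remodelling enzymes 33 of 35 rose and 2 fell (camera adjusted p = 1.21e-17, and 0.0354 with an estimated correlation), with Timp1 and Lox among them.

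Ribosomal genes were raised at both levels at day 3. Of the ribosome biogenesis genes 32 of 44 rose and 0 fell (camera adjusted p = 1.00e-07, and adjusted p = 0.341 with an estimated correlation). Of the cytosolic ribosomal proteins 24 of 33 rose and 0 fell (camera adjusted p = 1.30e-06, and adjusted p = 0.215 with an estimated correlation), with Rpl12 (1.28 ± 0.11) in front. All 42 oxidative phosphorylation genes fell (camera adjusted p = 9.98e-19, and adjusted p = 0.162 with an estimated correlation), with Cox7a1 (-1.88 ± 0.15) lowest. Ppargc1a (-2.97 ± 0.17), the coactivator that drives mitochondrial genes, fell to a level 7.83-fold below day 0. All 22 fast sarcomere genes fell (camera adjusted p = 7.45e-08, and adjusted p = 0.321 with an estimated correlation), with a median of -0.84, and the fast myosins were Myh4 (-0.57 ± 0.12), Myh1 (-0.54 ± 0.11) and Myh2 (-0.90 ± 0.15). Their transcripts sit close to the top of the arrays' range, Myh4 at 13.93 at day 0 against a maximum of 14.8, so their changes may be compressed. Myostatin fell by 3.11 ± 0.19, the ligase Fbxo32 (-1.02 ± 0.08) was lower, and Trim63 stood at -0.10 ± 0.09, which did not pass the test. The myogenic factor Myog (2.03 ± 0.17) and embryonic myosin Myh3 (1.77 ± 0.21) rose. Of the developmental sarcomere genes 10 of 13 rose and 1 fell (camera adjusted p = 0.000175, and adjusted p = 0.162 with an estimated correlation). Circadian clock genes fell in 12 of 17 cases and rose in 0 (camera adjusted p = 1.54e-05, and adjusted p = 0.215 with an estimated correlation), and Dbp (-1.87 ± 0.09) was lowest, at a time of day the labels do not give. The neutrophil receptor Cxcr2 was still raised (3.47 ± 0.35), although only 5 of 15 neutrophil markers passed the test (camera adjusted p = 0.162). Those markers include granule genes of developing neutrophils. Of 10 mature neutrophil genes, a list added after the data were seen, 7 rose and 0 fell at day 3, with a median of 2.11 (camera adjusted p = 0.000203, and adjusted p = 0.572 with an estimated correlation). The liver acute-phase gene Saa2 (-3.82 ± 0.86) was among the largest falls, and it had differed between the day 0 pools, with 11.27 on the log2 scale in the left pool and 7.997 in the right. Without the left pool of day 0 it fell by 2.18 and was still called. At day 3, 31 of the 39 lists kept their counts when adjusted over the list alone.

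At day 5 the developmental sarcomere genes and the matrix genes stood above day 0, as did mitosis genes and macrophage markers. Embryonic myosin Myh3 rose 18.3-fold. Perinatal myosin Myh8 (1.86 ± 0.20), cardiac actin Actc1 (2.43 ± 0.18) and cardiac troponin T Tnnt2 (3.05 ± 0.11) rose with it. Of the developmental sarcomere genes 12 of 13 rose and 1 fell (camera adjusted p = 5.78e-08, and adjusted p = 0.0540 with an estimated correlation). Of the satellite cell and myogenic regulators 14 of 25 rose and 6 fell (camera adjusted p = 0.00371, and adjusted p = 0.236 with an estimated correlation), led by Mymk (3.64 ± 0.13), the membrane protein that fuses myoblasts, and including Pax7 (0.44 ± 0.09). All 18 collagens rose (camera adjusted p = 4.14e-12, and adjusted p = 0.101 with an estimated correlation), with Col12a1 (3.07 ± 0.10) highest, and of the matrix glycoproteins and remodelling enzymes 33 of 35 rose and 0 fell (camera adjusted p = 3.89e-19, and 0.0354 with an estimated correlation), with Timp1 (4.88 ± 0.11) and Lox (4.18 ± 0.08). Of the growth factor, activin and myostatin signalling genes 25 of 39 rose and 7 fell (camera adjusted p = 3.52e-05, and adjusted p = 0.164 with an estimated correlation). Igf2 (2.52 ± 0.09) and Igf1 (1.22 ± 0.22) rose, and Mstn (-3.03 ± 0.19) and Vegfa (-1.38 ± 0.12) fell.

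The cell cycle genes were also up at day 5, with all 34 mitosis genes and 28 of 29 DNA replication genes higher than at day 0 (camera adjusted p = 9.50e-16, and adjusted p = 0.236 with an estimated correlation for mitosis). The replication list passed as well (camera adjusted p = 2.72e-11, and adjusted p = 0.236 with an estimated correlation). Within the day the mitosis genes were higher in the left pool, by a median of 0.37, and the fast sarcomere genes were higher in the right pool by the same amount, 0.37. Of the ribosomal proteins 28 of 33 rose and 0 fell (camera adjusted p = 1.21e-07, and adjusted p = 0.197 with an estimated correlation). Macrophage and monocyte markers rose in 28 of 30 cases and fell in 1 (camera adjusted p = 1.09e-16, and 0.0354 with an estimated correlation). All 21 tricarboxylic acid cycle genes fell (camera adjusted p = 1.72e-09, and adjusted p = 0.219 with an estimated correlation). In the glycolysis and glycogen list the phosphorylase kinase subunit Phkg1 (-2.73 ± 0.18) fell as well. All 26 genes of fatty acid uptake and oxidation fell (camera adjusted p = 5.40e-11, and adjusted p = 0.219 with an estimated correlation), among them Ppargc1a (-2.28 ± 0.17) and the lipid regulator Ppara (-2.15 ± 0.20). Adipocyte markers fell in 9 of 14 cases and rose in 2 (camera adjusted p = 0.0493, and adjusted p = 0.425 with an estimated correlation), with the lipid droplet protein Plin4 (-2.17 ± 0.09) lowest. The largest falls included Odf3l2 (-4.15 ± 0.12), Ostn (-3.72 ± 0.18), which encodes the muscle hormone osteocrin, Gdap1 (-3.65 ± 0.14) and Scn4b (-3.60 ± 0.19). The call of the adipocyte list is marginal, as its adjusted p was 0.0503 under quantile normalization, 0.0529 with equal array medians, 0.103 with the hepatocyte mean as a covariate, 0.0501 without the left pool of day 0 and 0.0867 without the right pool of day 5. It also ended without any single pool of day 3, 7, 10 or 14. Adjusted over the list alone, 33 of the 39 lists kept the same counts at day 5.

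At day 7, 13206 genes had changed, against 12980 at day 5. That order turned with the mean of the hepatocyte genes as a covariate (11212 against 11636). It also turned without either pool of day 7. Day 7 then rests on 1 pool and day 5 on 2, which lowers the precision at day 7 alone, so those fits cannot decide the order. Myh3 was the largest rise (4.82 ± 0.21, 28.2-fold), followed by C1qtnf3 (4.74 ± 0.21), a secreted protein of growing cartilage and connective tissue, Ms4a6d (4.60 ± 0.09) and the imprinted gene Mest (4.46 ± 0.12). All 34 mitosis genes rose, with a median of 2.49 (camera adjusted p = 4.47e-15, and adjusted p = 0.236 with an estimated correlation), with Bub1 (3.41 ± 0.22) and Mki67 (2.81 ± 0.38). All 18 collagens rose (camera adjusted p = 4.96e-13, and adjusted p = 0.0916 with an estimated correlation), with Col1a1 at 3.03 ± 0.09 and Col12a1 at 3.81 ± 0.10. Macrophage and monocyte markers were still raised in 27 of 30 cases and lower in 2 (camera adjusted p = 1.14e-14, and 0.0354 with an estimated correlation). The complement gene C1qb (2.99 ± 0.10), which is also in the macrophage list, rose among 8 of 12 complement components (camera adjusted p = 6.54e-05, and adjusted p = 0.219 with an estimated correlation). Neutrophil markers now went both ways, as 2 of 15 rose and 6 fell, and adjusted over the list alone 2 rose and 2 fell (camera adjusted p = 0.541). Against the same side at day 0 their median was -1.84 in the right pool and -0.26 in the left, and all 15 were higher in the right pool of day 0.

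Genes of energy metabolism and fast contraction were below day 0 at day 7. The median of the oxidative phosphorylation genes was -1.17, and all 42 fell (camera adjusted p = 4.12e-15, and adjusted p = 0.197 with an estimated correlation). That of the glycolysis and glycogen genes was -1.40, and all 22 fell (camera adjusted p = 8.15e-10, and adjusted p = 0.236 with an estimated correlation). Excitation-contraction coupling genes fell in 16 of 17 cases (camera adjusted p = 2.02e-06, and adjusted p = 0.310 with an estimated correlation), with the potassium channel Kcna7 (-2.92 ± 0.16) and the chloride channel Clcn1 (-2.59 ± 0.16). Of the fast sarcomere genes 0 of 22 rose and 21 fell (camera adjusted p = 1.13e-06, and adjusted p = 0.357 with an estimated correlation), with the kinase Mylk2 (-2.54 ± 0.14) and Pvalb (-1.16 ± 0.13) lower. Ckm (-0.90 ± 0.09), a member of the glycolysis and glycogen list, was lower too. The slow sarcomere list was divided, as 7 of 14 rose and 6 fell (camera adjusted p = 0.565; median -0.08, mean 0.07). The slow troponins Tnni1 (2.76 ± 0.25) and Tnnc1 (2.19 ± 0.32) rose, and the slow myosin light chains Myl3 (-3.37 ± 0.33) and Myl2 (-2.45 ± 0.35) fell. Both atrophy ligases were below day 0, Fbxo32 (-1.90 ± 0.08) and Trim63 (-1.27 ± 0.09), within a list of which 4 of 20 rose and 11 fell (camera adjusted p = 0.0514). Proteasome subunits changed little, as 3 of 30 rose and 8 fell with a median of -0.11 (camera adjusted p = 0.360). Of the neuromuscular junction and denervation genes 10 of 20 rose and 9 fell (camera adjusted p = 0.101). Runx1 (3.30 ± 0.10) and Myog (3.02 ± 0.17) rose, and the adult acetylcholine receptor subunit Chrne (-1.41 ± 0.11) fell. Of the 5 erythrocyte markers measured 3 fell and 0 rose (camera adjusted p = 0.0559), among them Alas2 (-1.54 ± 0.16). Against the same side at day 0 their median was -1.69 in the right pool and -0.14 in the left. At day 0 itself 4 of 5 were higher in the right pool. Hepatocyte genes, a list added after the data were seen, fell in 25 of 31 cases at day 7 (camera adjusted p = 0.0126, 0.860 with an estimated correlation; fry adjusted p = 0.114). They were 5.64-fold higher in the left than in the right pool of day 0. At day 7, 30 of the 39 lists kept their counts when adjusted over the list alone.

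The median, mean and camera direction of a list differed in sign in 15 pairs of list and day. Camera called none of them, and fry, which does not compare a list with other genes, called 8. At day 1 these were the collagens, lymphocyte markers, tendon markers and neuromuscular junction genes, and at day 3 the kinase inhibitors, tendon markers and Z-disc genes. At day 5 they were the kinase inhibitors and Z-disc genes, at day 7 the slow sarcomere genes, at day 10 the translation factors, Schwann cell markers and antioxidant genes, and at day 14 the proteasome subunits and Schwann cell markers. Over all 234 pairs of list and day camera called 158, 112 of them up and 46 down, and 23 of the calls held with an estimated correlation.

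Among the genes plotted by array, each was read by one probe set, with Ppargc1a the exception, for which the brighter of 2 was used. The probe sets were 10379511 for Ccl2, 10387536 for Cd68, 10568714 for Mki67, 10380419 for Col1a1, 10377018 for Myh3, 10349993 for Myog, 10346250 for Mstn, 10529979 for Ppargc1a, 10428796 for Fbxo32, 10365559 for Igf1, 10377117 for Myh4 and 10419934 for Myh7.

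**Figure D2:**
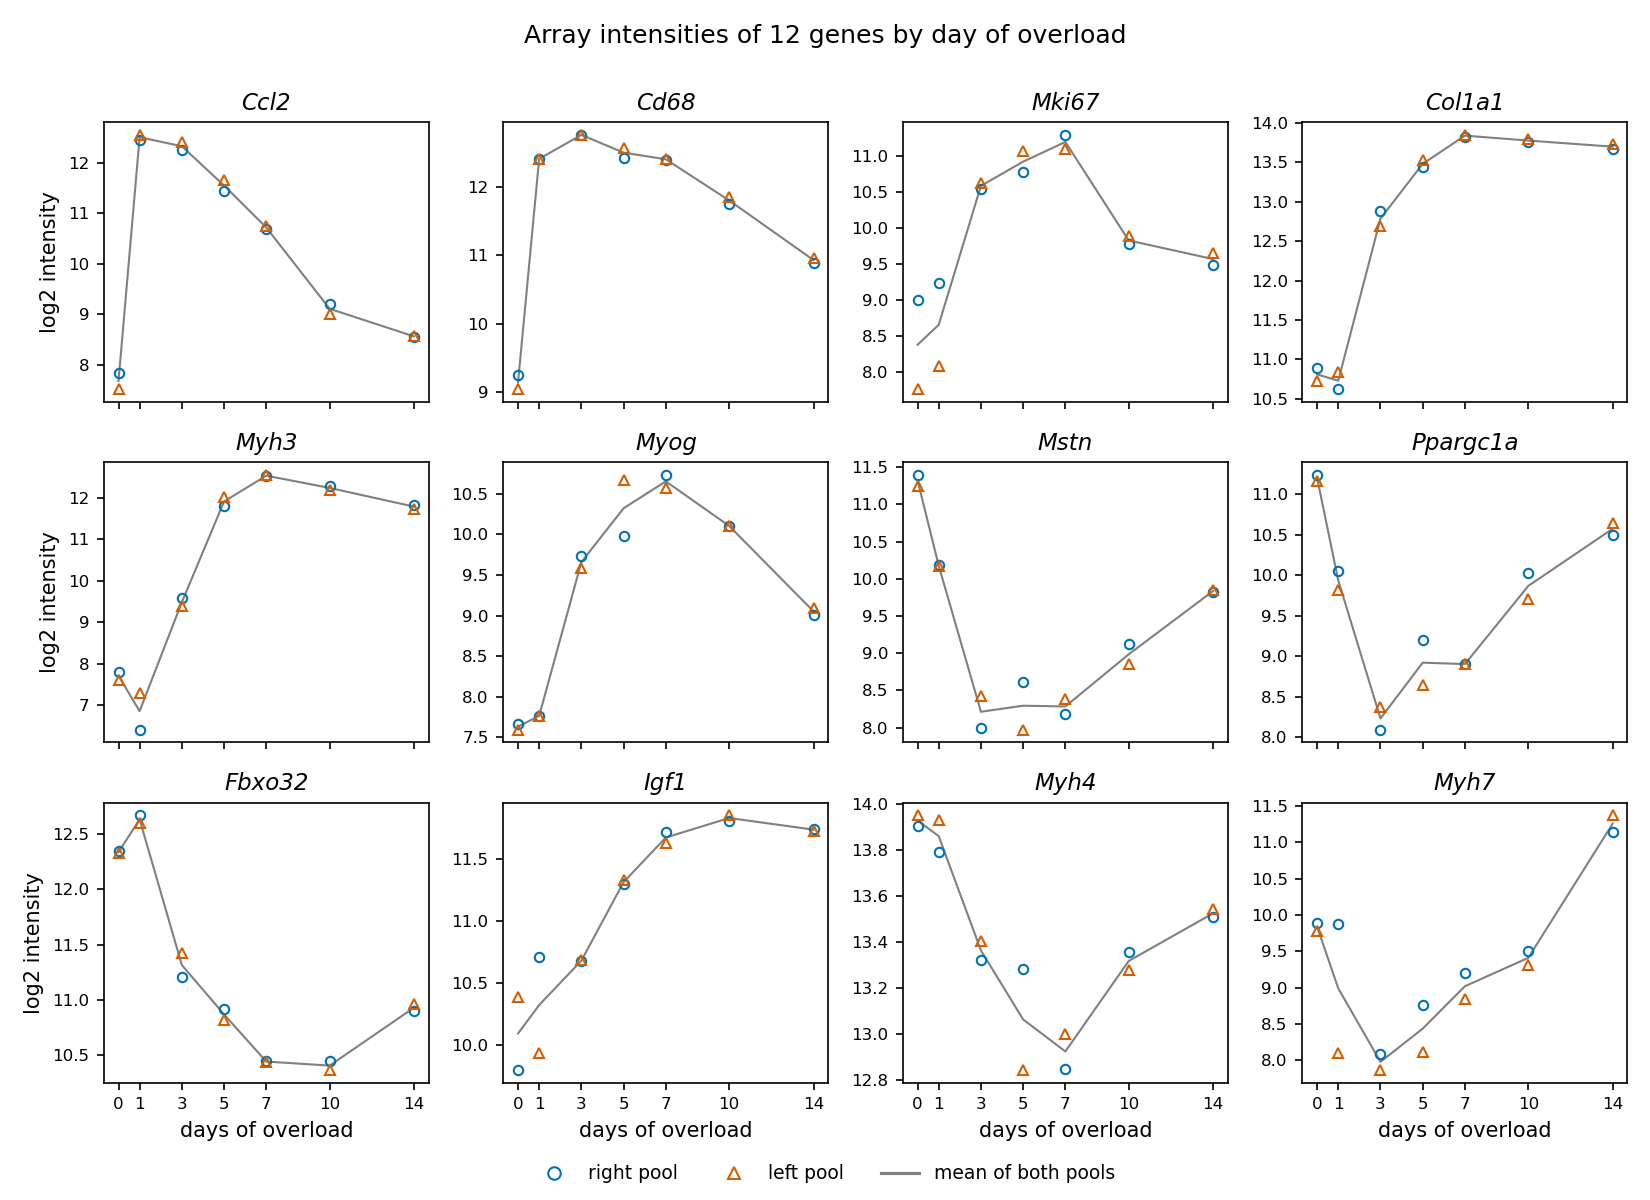
Log2 intensity (vertical axes) of 12 genes on each array against days of overload (horizontal axes), with circles for the right pool, triangles for the left pool and a line through their mean. Ccl2 was highest at day 1, Myh3 at day 7, and Myh7 at day 14, when both pools lay above both pools of day 0.

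At day 10, matrix, tendon and developmental muscle genes stood above day 0, as did mitosis genes, chemokines and macrophage markers. C1qtnf3 was the largest rise (4.86 ± 0.21), followed by Myh3 (4.52 ± 0.21), Mest (4.51 ± 0.12) and Cthrc1 (4.41 ± 0.09), a secreted protein of repairing tissue. All 18 collagens rose, at their highest median, 2.12 (camera adjusted p = 2.27e-16, and adjusted p = 0.0593 with an estimated correlation). Of the tendon markers 11 of 14 rose and 1 fell (camera adjusted p = 1.91e-06, and adjusted p = 0.110 with an estimated correlation), with tenomodulin Tnmd (3.04 ± 0.17) and Cilp (2.90 ± 0.12). Of the developmental sarcomere genes 12 of 13 rose and 1 fell (camera adjusted p = 1.55e-09, and 0.0354 with an estimated correlation). The mitosis genes rose in 30 of 34 cases and fell in 1, at a median of 1.10 (camera adjusted p = 6.89e-09, and adjusted p = 0.358 with an estimated correlation). Of the chemokines and cytokines 17 of 30 rose and 2 fell (camera adjusted p = 7.16e-07, and 0.0337 with an estimated correlation), with Ccl2 down to 1.43 ± 0.12. Macrophage and monocyte markers rose in 26 of 30 cases and fell in 2, at a median of 2.10 (camera adjusted p = 2.01e-15, and 0.0354 with an estimated correlation). Lymphocyte markers rose in 9 of 18 cases and fell in 2 (camera adjusted p = 0.0115, and adjusted p = 0.137 with an estimated correlation). Cd4 (1.25 ± 0.11) and the T cell receptor chain Cd3g (1.07 ± 0.11) rose, and the B cell gene Ms4a1 (-0.81 ± 0.10) fell. The lymphocyte call was lost without the dimmest of 3 equal classes of genes, with an adjusted p of 0.258.

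The ribosome biogenesis list did not pass the test at day 10, where 5 of 44 rose and 13 fell (camera adjusted p = 0.560), and Rrs1 (-0.89 ± 0.16) was among the lower ones. All 21 tricarboxylic acid cycle genes fell (camera adjusted p = 2.19e-09, and adjusted p = 0.219 with an estimated correlation), with a median of -0.82. Fast sarcomere genes fell in 13 of 22 cases (camera adjusted p = 0.00465, and adjusted p = 0.570 with an estimated correlation), while Myh1 stood at 0.06 ± 0.11 and Myh2 at -0.07 ± 0.15, which did not pass the test. Of the circadian clock genes 0 of 17 rose and 15 fell (camera adjusted p = 4.11e-05, and adjusted p = 0.219 with an estimated correlation), again at an unknown time of day. Neuromuscular junction and denervation genes rose in 10 of 20 cases and fell in 4 (camera adjusted p = 0.0186, and adjusted p = 0.258 with an estimated correlation). The liver genes Mup3 (-2.81 ± 1.07) and Fabp1 (-2.70 ± 0.97) were among the largest falls. Without the left pool of day 0 they stood at -1.69 and -1.52, without the right pool of day 10 at -1.93 and -2.09, and neither was called. With the mean of the hepatocyte genes as a covariate Mup3 stood at -0.75 and was not called, while Fabp1 kept its call. The covariate is itself a mean of liver genes, so a smaller fall with it does not decide the cause. Adjusted over the list alone, 26 of the 39 lists kept the same counts at day 10.

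At day 14 the muscle had not returned to its day 0 state, with 8394 genes called. The largest rises included C1qtnf3 (4.26 ± 0.21), Myh3 (4.07 ± 0.21), Mest (3.89 ± 0.12) and Sfrp2 (3.63 ± 0.16), a secreted Wnt modulator. All 35 matrix glycoproteins and remodelling enzymes rose (camera adjusted p = 2.36e-26, and 0.0337 with an estimated correlation), with periostin Postn (3.40 ± 0.17), and all 18 collagens rose (camera adjusted p = 1.32e-18, and 0.0469 with an estimated correlation). Fibro-adipogenic progenitor markers rose in 15 of 19 cases and fell in 1 (camera adjusted p = 3.37e-09, and adjusted p = 0.0731 with an estimated correlation). Endothelial markers rose in 17 of 20 and fell in 1 (camera adjusted p = 1.75e-06, and adjusted p = 0.246 with an estimated correlation), with Plvap (1.09 ± 0.07) and Apln (1.73 ± 0.12). Of the tendon markers 10 of 14 rose and 1 fell (camera adjusted p = 3.74e-07, and adjusted p = 0.0916 with an estimated correlation). Macrophage and monocyte markers rose in 25 of 30 cases and fell in 2 (camera adjusted p = 5.19e-15, and 0.0354 with an estimated correlation), and Cd68 was still 3.45-fold above day 0.

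Slow sarcomere genes now stood above day 0, as 9 of 14 rose and 1 fell (camera adjusted p = 0.000514, and adjusted p = 0.236 with an estimated correlation). Tnni1 (2.36 ± 0.25) and the slow calsequestrin Casq2 (1.88 ± 0.11) were highest, and Myl3 (-1.24 ± 0.33) fell, a call that ended without the right pool of day 14 (adjusted p = 0.0506). Slow myosin Myh7 (1.42 ± 0.42) rose, and its call ended on leaving out any pool of day 0 or 14, with 1.47 and 1.36 without the right or left pool of day 0 and 1.53 and 1.30 without the right or left pool of day 14. Of the fast sarcomere genes 1 of 22 rose and 10 fell (camera adjusted p = 0.0636), and Pvalb (-0.22 ± 0.13) did not pass the test. Ckm (-0.21 ± 0.09), of the glycolysis and glycogen list, did not pass it either. The growth factor, activin and myostatin signalling list rose in 24 of 39 cases and fell in 5 (camera adjusted p = 1.21e-06, and adjusted p = 0.110 with an estimated correlation). Igf2 (2.64 ± 0.09), Igf1 (1.65 ± 0.22) and the myostatin antagonist follistatin, Fst (1.20 ± 0.09), rose, and Mstn (-1.49 ± 0.19) fell. Oxidative phosphorylation genes fell in 37 of 42 cases (camera adjusted p = 2.81e-11, and adjusted p = 0.221 with an estimated correlation), and adjusted over the list alone in 40. The mitosis genes rose in 24 of 34 cases and fell in 1 (camera adjusted p = 7.70e-07, and adjusted p = 0.430 with an estimated correlation), and adjusted over the list alone 29 rose and 1 fell. Of the neuromuscular junction and denervation genes 11 of 20 rose and 7 fell (camera adjusted p = 0.0188, and adjusted p = 0.258 with an estimated correlation). Erythrocyte markers fell in 3 of 5 cases (camera adjusted p = 0.0294, and adjusted p = 0.334 with an estimated correlation), a call that ended without the right pool of day 0 (adjusted p = 0.0762) or of day 14 (adjusted p = 0.0509). Liver acute-phase and plasma protein genes were among the largest falls, with Orm1 (-2.73 ± 0.98), Hrg (-2.72 ± 1.00) and Itih4 (-2.44 ± 0.85), and with the hepatocyte mean as a covariate they stood at -0.64, -0.52 and -0.60 and were not called. Their calls also ended without the left pool of day 0 (-1.16, -1.18 and -1.04), the right pool of day 14 (-2.85, -3.13 and -2.74) or the left pool of day 14 (-2.61, -2.32 and -2.14). Adjusted over the list alone, 20 of the 39 lists kept the same counts at day 14, and no list differed by more than 5 members.

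The comparisons between consecutive days were made gene by gene, and gene lists were not tested in them. From day 1 to day 3, 6920 genes changed (4284 rose and 2636 fell), with the Wnt modulator Sfrp2 (3.91 ± 0.16), Cthrc1 (2.80 ± 0.09) and the mitotic kinase Plk1 (2.72 ± 0.18) rising and the macrophage metabolic enzyme Acod1 (-2.88 ± 0.13), the interferon gene Ifit3b (-2.63 ± 0.18) and the chemokine Cxcl2 (-2.50 ± 0.28) falling. From day 3 to day 5, 2225 genes changed, with Myh3 (2.43 ± 0.21), Tecrl (2.61 ± 0.21) and Igf2 (2.11 ± 0.09) rising and the interleukin 1 family gene Il1f9 (-1.85 ± 0.26) and the long noncoding RNA Mirt2 (-1.95 ± 0.32) falling. Without 1 array this count was 697 (day 3 right), 1204 (day 3 left) or 790 (day 5 left). From day 5 to day 7, 230 genes changed, among them Tnmd (1.42 ± 0.17) and Ptn (1.37 ± 0.12), both of which rose. This number came to 29 without the right pool of day 5, 21 without the right pool of day 7 and 60 without the left pool of day 7.

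From day 7 to day 10, 3284 genes changed (1385 rose and 1899 fell). The larger share fell, but 50.4% rose under quantile normalization, 50.2% without the right pool of day 7 and 52.4% without the left pool of day 10. The prostaglandin synthase Ptgs2 (-1.79 ± 0.11) and the mitotic genes Bub1 (-1.74 ± 0.22) and Hmmr (-1.72 ± 0.21) fell, and the muscle ribosomal protein Rpl3l (1.54 ± 0.21) and the mitochondrial creatine kinase Ckmt2 (1.41 ± 0.19) rose. The count was 965 without the right pool of day 7, 1290 without the right pool of day 10 and 1478 without the left pool of day 10. From day 10 to day 14, 931 genes changed (420 rose and 511 fell), with the complement gene C7 (1.31 ± 0.17) rising and Ccl3 (-1.89 ± 0.15) and Tyrobp (-1.22 ± 0.15) falling. The larger share fell, but 50.3% rose under quantile normalization and 56.5% without the right pool of day 14. That count was 128 and 67 without the right or the left pool of day 10, and 200 and 79 without the right or the left pool of day 14. Day 14 against day 3 contrasts late with early overload directly, and 6765 genes changed (3510 rose and 3255 fell). The larger share rose, but only 48.1% did with equal array medians and 49.5% without the left pool of day 14. Tnmd (3.79 ± 0.17), slow myosin Myh7 (3.27 ± 0.42) and Sfrp4 (3.20 ± 0.12) were higher late, and Arg1 (-4.66 ± 0.43), Ccl2 (-3.77 ± 0.12) and Cxcr2 (-3.71 ± 0.35) were higher early.

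Among the 4441 genes past the F test with at least a 2-fold difference between their highest and lowest day mean, the highest mean fell at day 0 for 25.2%, day 7 for 24.0%, day 1 for 21.4%, day 3 for 8.83%, day 10 for 8.78%, day 14 for 7.14% and day 5 for 4.71%. The lowest mean fell at day 0 for 43.6%, at day 1 for 22.8% and at day 7 for 17.0%, and at days 3, 5, 10 and 14 for 8.13%, 1.67%, 4.01% and 2.84%. These shares are descriptive and carry no test. The share with the highest mean at day 5 was 1.49% in the right pools alone and 18.1% in the left pools alone. That for day 7 was 29.1% in the right and 11.1% in the left pools alone, so the places of days 5 and 7 rest on single pools. The share with the lowest mean at day 5 was 1.40% in the right and 7.14% in the left pools alone.

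Across days, the test of right against left pools gave 0 genes called by limma. Of 19938 genes, 586 had an unadjusted p under 0.05, fewer than that threshold gives with no difference. Differences that change side from day to day count as residual spread in this test, so the 0 does not show that the pools were alike. Within single days the right and left pools did differ, which is described here and was not tested. The log2 difference between the right and left pools had an SD over genes of 0.299 at day 0 and 0.317 at day 1, against 0.158 to 0.215 at the later days, and the correlation across genes was 0.987 and 0.986 at days 0 and 1 and at least 0.994 later. More than 2-fold apart were 277 genes at day 0 and 384 at day 1, against 11 to 92 at the later days. All 31 measured hepatocyte genes, from albumin to fibrinogen, were higher in the left pool of day 0 and in the right pool of day 1, with median right-left differences of -2.50 and 2.11 on the log2 scale. Albumin itself (Alb) read 12.75 on the right and 13.82 on the left at day 0, and its lowest reading was 10.49, in the right pool of day 5.

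**Figure D3:**
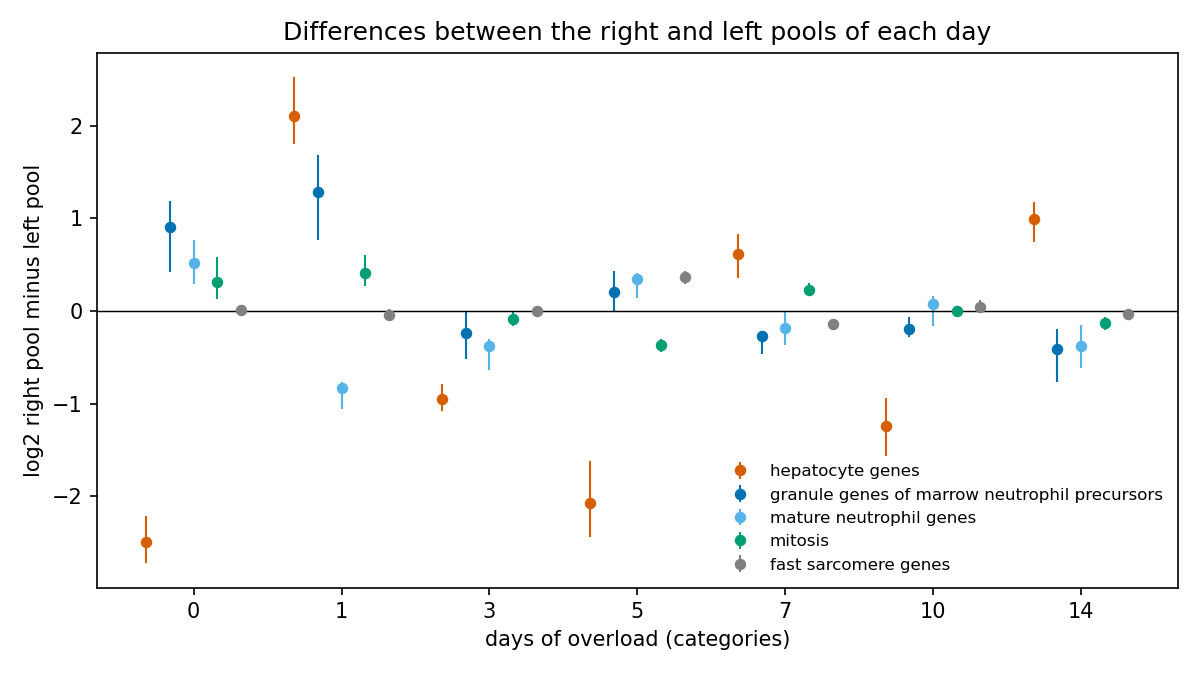
Median log2 difference between the right and the left pool of each day (vertical axis, points with bars from the lower to the upper quartile of the list's genes) for 5 gene lists, by day of overload (horizontal axis, categories). Hepatocyte genes differed most, by -2.50 at day 0 and 2.11 at day 1, while fast sarcomere genes differed most at day 5, by 0.37.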

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

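All tests of explanations in this part were chosen after the results they concern were seen.

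Probe sets with no gene symbol or with several are outside the comparisons of genes above, and there are no control samples of background for them. Of 13767 such probe sets, 934 changed by more than 2-fold at an adjusted p under 0.05 at day 1, 794 at day 3, 1001 at day 5, 1195 at day 7, 604 at day 10 and 343 at day 14. Rises outnumbered falls at each of these days, for example 834 against 100 at day 1 and 285 against 58 at day 14. No single gene can be given for them.

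Genes of hepatocytes differed between the right and left pools of a day. All 31 measured members were higher in the left pool of day 0 and in the right pool of day 1, so the lower of both shares was 100%. A difference in scaling is argued against, since all other genes had a median right-left difference of 0.04864 at day 0. A response to overload is argued against too, since the median of the hepatocyte genes was -2.496 at day 0, before any overload. Albumin ranged from 10.49 to 14.00 on the log2 scale over the arrays. How many of these genes muscle itself expresses was not measured, as no array is known to be free of hepatocyte RNA. RNA of hepatocytes in some pools remains open. The share of 100% decides nothing about it, since the list was drawn up after liver genes were seen among the largest changes and the share restates the pattern. No biological explanation other than a response to overload was tested.

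Granule genes of neutrophil precursors were higher in the right pools of days 0 and 1, in 10 of 10 genes at each day, with medians of 0.91 and 1.28, and Mpo read 9.86 on the right and 8.19 on the left at day 0. At day 1 the genes of mature neutrophils were higher in the left pool, with a median of -0.8323. This argues against a larger total of mature neutrophils in the right pool of that day. Against day 0 these genes had risen in 10 of 10 cases at day 1, by a median of 3.22. A smaller difference in blood neutrophils could be hidden by that rise, so blood neutrophils remain open at day 1. At day 0 mature neutrophil genes were also higher on the right, with a median of 0.5201, so blood neutrophils remain open there too. Bone marrow cells or their RNA remain open at both days, and the mitosis genes that dividing marrow cells carry were higher in the right pools, with a lower median of 0.3135. That last value is weak evidence, since mitosis genes differed by -0.37 at day 5, where the granule genes differed by 0.20.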

How the results depend on the processing

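The hepatocyte covariate and the fit without the left pool of day 0 and the right pool of day 1 were chosen after the data were seen, and the other alternatives before. Unless stated, the cause of a difference was not tested.

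Quantile normalization, equal array medians, averaging probe sets and a robust prior left every count of changed genes within 1.5 times. The step from day 5 to day 7 came to 363 genes without the dimmest of 3 equal classes, 101 with all probe sets, 383 with a trended prior and 93 with only the arrays of the 2 days. Day 14 against day 10 came to 1544 without the dimmest class and 1431 with a trended prior, and day 5 against day 3 to 1424 with only the arrays of both days, where fewer arrays estimate the spread.

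A stricter threshold lowers counts by construction. With a 2-fold change they were 1852, 2356, 2579, 3043, 1842 and 1233 against day 0 in order of day, 714, 143, 15, 175 and 14 for consecutive days, and 1021 for day 14 against day 3. With treat against 1.5-fold they were 2327, 2885, 3153, 3557, 2209 and 1356, then 680, 74, 0, 3 and 1, and 1062.

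Leaving out each array gave ranges of 9339 to 10942 genes at day 1, 7936 to 9644 at day 3, 9963 to 13390 at day 5, 9881 to 13513 at day 7, 7606 to 10531 at day 10 and 6052 to 8717 at day 14. Consecutive days gave 4659 to 6999, 697 to 2333, 21 to 327, 965 to 3393 and 67 to 1168. Day 14 against day 3 gave 5254 to 6907, the F test 13067 to 14178, and side 0 throughout.

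With side as replicate block day 7 against day 0 gave 12932 genes and day 7 against day 5 gave 173, and 1015 of the 1023 pairs of named gene and comparison kept direction and call while 8 lost the call. These were Bub1 at day 1, Igf1 at day 3, Mup3, Chil3 and Ngp at day 10, Hrg and Psmd4 at day 14, and Sprr1a from day 5 to day 7, with adjusted p from 0.0519 to 0.0619 (Mup3 0.0544). The numbers do not pair the pools across days, since the right pools' deviations correlated between -0.583 and 0.438, with a median of -0.0624.

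Camera called 158 of 234 pairs of list and day, and 23 with an estimated correlation. Under quantile normalization 225 pairs kept direction and call, 5 lost the call and 4 gained it. Without the dimmest class 210 kept both, 17 lost the call and 7 gained it. Fry, which does not compare a list with other genes, called 204 pairs. Of these, camera gave 46 the same direction without a call and 1 the opposite direction without a call, and 1 camera call was not made by fry.

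With the hepatocyte covariate 11042, 9522, 11636, 11212, 9205 and 7233 genes changed against day 0. Without both pools the proliferation gene Mki67 reversed at day 1, from 0.28 (adjusted p = 0.55) to -0.92 (adjusted p = 0.00104), where the comparison rests on 1 pool per day.

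With genes of at least 1.5-fold, 8860 genes were described and 4.55% had their lowest mean at day 5. In the right pools alone 1.49% had their highest mean at day 5. In the left pools alone 18.1% had it at day 5 and 11.1% at day 7, and 7.14% had their lowest at day 5.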

Other observations

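The imprinted gene list and the values in this part were chosen after the data were seen.

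Imprinted genes, expressed from one parental copy, went both ways during overload. Of 37 measured, 6 rose and 15 fell at day 1, 16 rose and 6 fell at day 3, 22 rose and 7 fell at day 5, 23 rose and 8 fell at day 7, 23 rose and 6 fell at day 10, and 24 rose and 6 fell at day 14. At day 14 the camera adjusted p was 1.87e-07, and 0.118 with an estimated correlation. The largest rises at that day included Mest (3.89 ± 0.12), Meg3 (3.36 ± 0.10), Plagl1 (3.29 ± 0.10) and Igf2 (2.64 ± 0.09), and Slc38a4 (-1.17 ± 0.14) fell. The list was written after several of its members had been seen among the largest rises, so its test is not independent evidence.

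Within days, 351 genes followed the mean of the hepatocyte genes at an adjusted p under 0.05, and 347 of them rose with it. The 31 measured hepatocyte genes make up that mean, so any of them in this count rise with it by construction. Of the genes called against day 0 at day 7, 10742 were also called with that mean as a covariate.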
